A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

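Scar tissue from the ears of 6 female New Zealand White rabbits was profiled by RNA sequencing at day 21. Full-thickness wounds, 6 on each ear, had been treated in 3 rabbits with saline (control) and in 3 rabbits with ADSC-Exos, which are exosomes, small secreted vesicles, from adipose-derived stem cells, at 100 µg in 2 ml. The series text puts the application in the first 3 days after injury, whereas the sample labels speak of 21 days, and the sources used here do not settle this. The rabbits were assigned to the arms at random, so each replicate is a separate animal. How the wounds of a rabbit were combined into its library is not given in the sources used here.

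Reads were handled with FastQC 1.0.0, Trimmomatic 0.40, STAR 2.7.6a, HTSeq 2.0.3 and DESeq2 1.30.1, per the submitters' processing notes, which give these names without roles. The genome build is not given in the sources used here, and coordinates are printed as the authors' tables give them. Gene symbols were taken from the deposited tables: 100 of 421 mRNA transcripts had none, and the lncRNA table pairs its transcript identifiers with no symbol. No column of per-sample values was left unmapped. All columns carry 1 date tag and 1 lane in their names, so no batch was visible.

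The values the authors deposited are on a log2 scale. Raising 2 to the value and subtracting 1 gave whole multiples of 1 step in each library, within 0.01 of a whole number for 100% of values in every column, so each deposited value is log2 of reads divided by a size factor, plus a pseudocount of 1. Those reads are called normalized reads after division. The authors' deposited p-values and FDR (p adjusted for the number of features tested) come from a comparison whose test the tables do not name. The authors' log2 fold change equals the mean of the ADSC-Exos log2 values minus that of the controls, so a fold is on the log2(normalized reads + 1) scale and understates the change of low features. Every mRNA and lncRNA in the deposited tables has an absolute log2 fold change over 1 and a p-value under 0.05, and every circRNA has an absolute log2 fold change over 1. The tables used here are therefore a selection. Ratios of the deposited FDR to p fit 17743 transcripts tested for mRNA and lncRNA together, with 53.4% of the ratios within 0.0001 of a whole rank. Of the 258 other transcripts, 197 share their FDR with another listed transcript, as ties of the adjustment do, and 61 do not.

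Library totals are unknown, since only selected features are held. Reads in the listed mRNAs ranged from 86844 to 224554 per rabbit, in the listed lncRNAs from 33593 to 47818, and in the listed circRNAs from 856 to 1592. The size factors of the mRNA and lncRNA tables ranged from 0.890 to 1.18. Those of the circRNA table were 0.510 in 5 rabbits and 0.454 in ADSC-Exos rabbit 1. A count of 0 allows up to 3 reads, and folds against an arm with no reads were computed against 3 reads in each rabbit. Such bounds cover counting error only.

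The 2 arms were compared with limma 3.58.1 in R 4.3.3 (trend and robust options) on the deposited log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. For mRNA and lncRNA the adjustment was made over 17743 transcripts, with each unlisted transcript given a p of 1 and each table adjusted separately. That can be too strict, since the ranks of the authors' p-values run to 1370 while 554 transcripts are listed. With no effect, 887 of 17743 transcripts would be expected at a p under 0.05. For circRNA the adjustment was made over the table, as the number tested is not known. The features had been selected by the authors' comparison of the same rabbits, so the limma p-values are not independent of it, and limma's prior for the spread comes from selected features. The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The adjustment over 17743 and a filter at a mean of 1 normalized read in the higher arm were settled only afterwards, following a first limma run without them. The filter removes no feature from the main fits. The whole reads recovered from the log2 values were not put through a count test.

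The script was tested on simulated data for 421 transcripts with 200 changed. Adjusted over 17743, it recovered 2% of 2-fold, 70% of 4-fold, 98% of 8-fold and 100% of 16-fold changes, and called 0% of unchanged transcripts. Adjusted over the table, it recovered 42%, 98%, 100% and 100%, and called 1.81% of unchanged transcripts. All simulated transcripts shared 1 fixed spread between rabbits, low means were raised, and none was made to be silent in single rabbits. These shares are therefore not the power in the real data, where TMEM102, at a log2 difference of -4.92, did not pass. With 3 rabbits against 3, an exact permutation test of 1 transcript cannot give a p under 0.1.

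The named genes are the 10 mRNAs with the largest rise and the 10 with the largest fall among calls with arms that do not overlap, at least 1 normalized read on average in the higher arm and a symbol, the 3 and 3 such lncRNAs, and up to 4 members of each gene list. Where fewer than 5 features pass limma, the 10 with the smallest p stand instead. As limma called fewer than 5 in each table, both the 10 smallest p and the authors' calls (FDR under 0.05) were used, a choice made after the limma counts were seen. Members of 30 gene lists were counted by direction and compared with the other listed mRNAs by Fisher's exact test, since a set test on selected features would be circular. Further genes named because of their values are said to be so chosen. Other calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

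Alternatives were quantile normalization, no size factor, other size factors, no filter, a filter at 10 normalized reads, limma without its trend and robust options, pseudocounts of 0.1 and 0.01, the replicate number as a block, other thresholds and leaving out each rabbit. TGFB1, named in the series title, and miRNAs were not analysed here. Results for 2 genes are not reported here, and the erythroid set described leaves 1 of them out, a choice unrelated to its values.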

Results

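Rabbit ear scars treated with ADSC-Exos or with saline were compared at day 21, with 3 rabbits in each arm. The tables held 421 mRNA transcripts of 415 genes, 133 long noncoding RNAs (lncRNAs) and 1694 circular RNAs (circRNAs, closed by back-splicing), each already selected by the authors for a difference between the arms. A gene name stands for its listed transcript, and other transcripts of the gene were not analysed here. Values are log2(normalized reads + 1), given as mean ± SD over 3 rabbits per arm, and differences are ADSC-Exos minus control. Reads in the listed mRNAs came to 131304 ± 27933 in the controls and 178355 ± 79252 in the ADSC-Exos rabbits (SD, n = 3).

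The first comparison asked which mRNAs differed in scars that had received exosomes. PTPRU, a receptor tyrosine phosphatase, was at 3.94 ± 0.07 in control and 5.89 ± 0.18 in ADSC-Exos scars, a difference of 1.95 (SE 0.11). COL10A1, the collagen of hypertrophic cartilage, was at 13.95 ± 0.80 in control and 12.07 ± 0.58 in ADSC-Exos scars, a difference of -1.88 (SE 0.57). HBB2, a beta globin, and ALAS2, the first enzyme of erythroid haem synthesis, were lower by differences of -1.71 (SE 0.64) and -1.91 (SE 0.73). Of the 421 mRNAs, 49 in the authors' deposited table had an FDR under 0.05, 22 higher and 27 lower. The arms did not overlap for 39 of these calls, 15 higher and 24 lower. Among all 421 listed mRNAs the share was 53.7%, so selection already favours such a separation. The 10% that chance gives holds for transcripts that were not selected, and so does not apply here.

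Among the mRNAs called higher in the authors' deposited table, the transcript with the largest difference and arms that do not overlap was one of EXOC3L1, at 4.96 with an FDR of 0.00013. Another EXOC3L1 transcript went the opposite way, from 22.3 normalized reads in control scars to none in ADSC-Exos scars, at least 7.39-fold lower, so the 2 transcripts had no common direction; their sum differed by 0.94 (SE 0.51), and by 0.43 without ADSC-Exos rabbit 3. RCVRN, the photoreceptor protein recoverin, had no reads in control rabbits and 5, 38 and 22 reads in ADSC-Exos rabbits, at least 7.40-fold higher, or 4.62-fold without ADSC-Exos rabbit 2. ATP6V0D2, a subunit of the vacuolar proton pump, averaged 15.3 normalized reads in control and 299.5 in ADSC-Exos scars, with log2 values of 4.03 ± 0.13 and 7.09 ± 2.23. Its reads were 77, 772 and 40 in the ADSC-Exos rabbits, and without ADSC-Exos rabbit 2 its log2 difference went from 3.07 to 1.81. PDK4, a kinase that inhibits pyruvate dehydrogenase, was at 10.25 ± 0.44 and 11.90 ± 1.16. The carboxylesterase gene CES4A was at 8.43 ± 0.47 and 10.33 ± 1.08, and the glutamate transporter gene SLC1A1 at 8.36 ± 0.53 and 9.62 ± 0.38. TNNT2, cardiac troponin T, differed by 1.95 (SE 0.66), GPR151 by 3.22 (SE 0.89) and ANKDD1A by 1.59 (SE 0.34). The authors' deposited table gave PDK4 an FDR of 0.029, CES4A 0.0058, SLC1A1 0.022 and TNNT2 0.046.

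Among the mRNAs called lower whose arms do not overlap, TMEM102 had the largest difference, -4.92 (SE 0.57), from 41.1 to 0.34 normalized reads. PMP2, a protein of peripheral myelin, was at 7.62 ± 0.69 in control and 5.03 ± 0.90 in ADSC-Exos scars. SLC7A10, a neutral amino acid transporter, differed by -2.33 (SE 0.51), LBP, the lipopolysaccharide-binding protein, by -2.19 (SE 0.57), and UNC5D, a netrin receptor, by -2.00 (SE 0.34). The ephrin receptor gene EPHA6 differed by -3.63 (SE 0.76). MYH7, a slow muscle myosin heavy chain, differed by -3.65 (SE 1.50). Its reads were 43, 148 and 5 in control and 0, 2 and 5 in ADSC-Exos rabbits, so its arms separate only through the size factors. The authors' deposited table gave PMP2 an FDR of 0.0023, LBP 0.0035, UNC5D 0.0017 and COL10A1 0.0017.

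**Figure D1:**
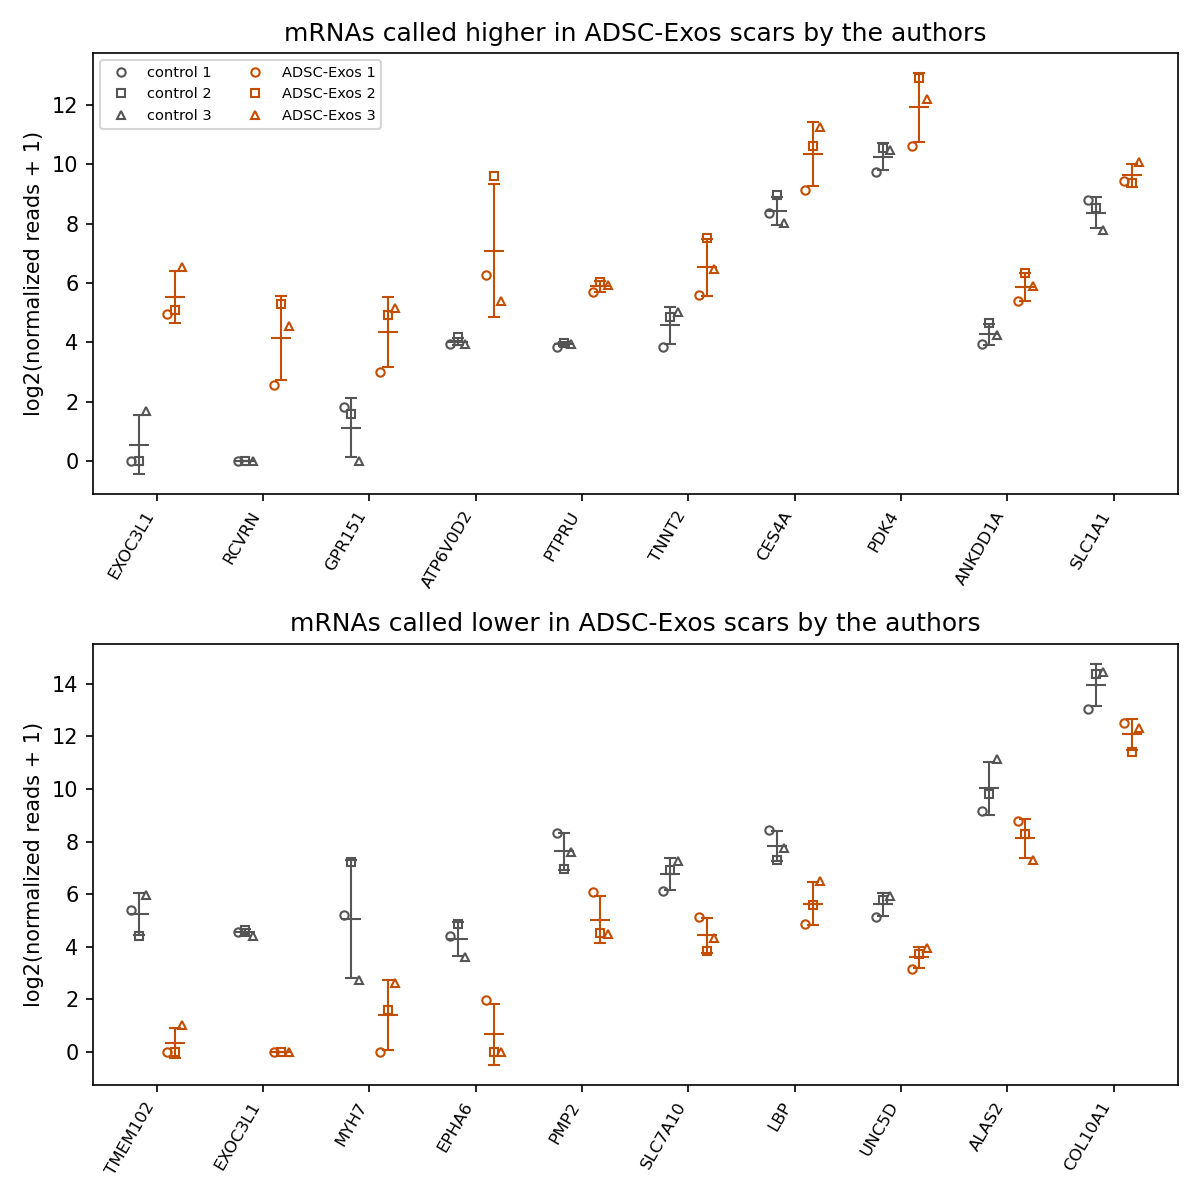
Log2(normalized reads + 1) of the 10 mRNAs with a symbol and the largest differences in each direction among the authors' calls with arms that do not overlap. Symbols are single rabbits, 3 control (grey) and 3 ADSC-Exos (orange); horizontal ticks are means and bars are SDs. PTPRU lies at 3.94 ± 0.07 in control and 5.89 ± 0.18 in ADSC-Exos scars, and ATP6V0D2 spreads more widely among the treated rabbits (SD 2.23).

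Of the 30 gene lists, 12 had members among the listed mRNAs, 17 genes in all. The erythrocyte list had 4 listed transcripts, of HBB2, ALAS2 and CA1, and all 4 were lower, 2 of them called in the authors' deposited table. Its direction did not pass the test against the other listed mRNAs (Fisher's exact test, two-sided, p = 0.032; adjusted p = 0.38 over 12 lists). CA1, the red cell carbonic anhydrase, was at 6.11 ± 0.79 in control and 4.01 ± 1.24 in ADSC-Exos scars, a difference of -2.10, or -1.40 without ADSC-Exos rabbit 3. The skeletal muscle list had MYH1 and MYH7, both called lower in the authors' deposited table, and the MYH1 arms overlapped (116, 99 and 2 reads in control rabbits). MYH1 differed by -2.87, and by -4.52 without control rabbit 3. Outside the list, TNNT2 was called higher (1.95), so called muscle transcripts went both ways. Of the cartilage list, COL10A1 was called lower, while EPYC at -1.52 (SE 0.89; -1.01 without control rabbit 3) and SCRG1 at 1.23 (SE 0.38) were not called. MC5R, the melanocortin receptor of sebaceous glands, was called lower, by a difference of -1.70 (SE 0.51).

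The matrix and TGF-beta response lists had few listed members and none was called. CTHRC1, a secreted protein of collagen-producing cells, differed by 2.41 (SE 2.72), by 0.61 without ADSC-Exos rabbit 3 and by 4.93 without rabbit 1. The oxidase gene NOX4 was at 4.80 ± 0.24 and 5.88 ± 1.52, and the macrophage elastase gene MMP12 at 5.74 ± 0.83 and 7.29 ± 1.92. The NOX4 difference of 1.09 was 0.41 without ADSC-Exos rabbit 3 and 1.91 without rabbit 1, and the MMP12 difference of 1.55 was 0.49 without ADSC-Exos rabbit 2 and 2.36 without rabbit 1. The macrophage scavenger receptor gene MSR1 differed by 1.29 (SE 0.73; 1.98 without ADSC-Exos rabbit 1), the keratinocyte transglutaminase gene TGM5 by 1.21 (SE 0.68; 0.68 without ADSC-Exos rabbit 2) and the chemokine gene CXCL10 by -1.44 (SE 0.76; -0.84 without ADSC-Exos rabbit 2). The 2 S100A8 transcripts, of the wound-activated keratinocyte list, differed by -1.15 (SE 1.15) and -1.34 (SE 1.22), and by -0.08 and -0.19 without control rabbit 3, which had 350 and 1023 reads. For each of these genes the arms overlapped. The other 18 lists, among them fibrillar collagens, TGF-beta pathway components, myofibroblast genes and reported miR-194 targets, had 0 members among the selected mRNAs used here, so levels of their genes were not analysed here.

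**Figure D2:**
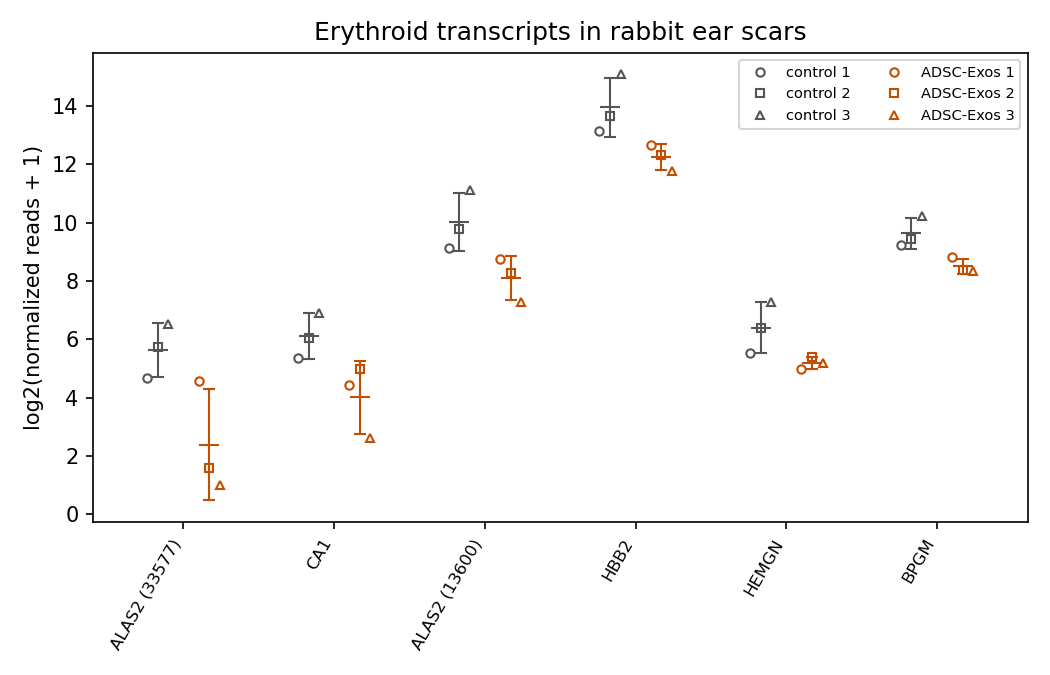
Log2(normalized reads + 1) of 6 erythroid transcripts, 4 from the fixed erythrocyte list (HBB2, CA1 and 2 ALAS2 transcripts) and those of BPGM and HEMGN chosen after their values were seen. Symbols are single rabbits, ticks are means and bars are SDs (n = 3 per arm). All 6 means are lower in ADSC-Exos scars, where HBB2 differs by -1.71 and BPGM by -1.13.

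By limma, 0 of the 421 mRNAs passed an adjusted p of 0.05 over 17743 transcripts, and 3 passed when adjusted over the table alone. At an unadjusted p under 0.05 there were 193, 94 higher and 99 lower. Those with the smallest limma p, the 2 EXOC3L1 transcripts, TMEM102, RCVRN, GPR135, CCDC63, 3 transcripts without a symbol, and FGF16 and MS4A10 at the same p, did not pass. GPR135 was at least 2.43-fold and FGF16 at least 1.95-fold lower, and CCDC63 at least 2.16-fold higher. Without ADSC-Exos rabbit 1 the count at an unadjusted p under 0.05 was 311, and it was 91 without ADSC-Exos rabbit 3.

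Of the mRNA calls in the authors' deposited table, 10 had overlapping arms. For 5 of these, reads of the listed transcript came from 1 rabbit: a transcript of RPL14 had 2127 reads and one of ABL2 1263 in ADSC-Exos rabbit 3, one of FZD1 had 1786 in ADSC-Exos rabbit 1, and one of CRLS1 and a transcript without a symbol had 443 and 310 in ADSC-Exos rabbit 2. SSR1 had 1886 and 1667 reads in control rabbits 2 and 3 and 9 in control rabbit 1, and SESTD1 had 1131 and 1301 in control rabbits 1 and 2 and 46 in control rabbit 3. TRPV5, a calcium channel, and COL22A1, a collagen of tissue junctions, had their high values in ADSC-Exos rabbits 2 and 3, TRPV5 at 1211 and 782 reads against 115 in ADSC-Exos rabbit 1. These transcripts were named after their values were seen.

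The second comparison asked the same of lncRNAs. MSTRG.8344.3 had no reads in control rabbits and 53, 4192 and 3405 reads in the ADSC-Exos rabbits. Its mean was at least 872-fold higher, or 594-fold without ADSC-Exos rabbit 2. Another transcript of that locus, MSTRG.8344.5, had 7283, 4425 and 6393 reads in control and 1155, 2206 and 2386 in ADSC-Exos rabbits, and was called lower in the authors' deposited table (-1.66, FDR 0.00015). The sum of the 4 listed transcripts of the locus was at 12.94 ± 0.43 in control and 11.81 ± 1.37 in ADSC-Exos scars with overlapping arms, a difference of -1.13, or -0.34 without ADSC-Exos rabbit 1. Sums cover listed transcripts only, so the total of a locus is unknown, and they were taken after the values were seen. MSTRG.11040.1 and MSTRG.18813.1 also had reads in ADSC-Exos rabbits alone (33, 13 and 11; 5, 39 and 21), at least 6.42-fold and 7.40-fold higher, or 4.11-fold without rabbit 1 and 4.44-fold without rabbit 2. MSTRG.6577.1 was at 4.51 ± 0.25 in control and 0.53 ± 0.93 in ADSC-Exos scars, and MSTRG.2167.1 at 4.32 ± 0.43 and 1.44 ± 1.26. MSTRG.10435.47 differed by -4.38 (SE 2.51), and by -2.08 without control rabbit 2. It had 24, 796 and 1 reads in control and 1, 1 and 0 in ADSC-Exos rabbits, so its arms separate only through the size factors. Its locus had 3 listed transcripts whose sum had overlapping arms. Of the 133 lncRNAs, 43 in the authors' deposited table had an FDR under 0.05, 19 higher and 24 lower.

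The arms did not overlap for 19 of those 43 lncRNA calls, 9 higher and 10 lower (chance gives 10% without selection), and 19 of the 43 had reads in 1 rabbit only. Limma called 0 lncRNAs, with 37 at an unadjusted p under 0.05 and 1 passing when adjusted over the table alone. The 10 with the smallest limma p, which did not pass, included MSTRG.8344.3, MSTRG.2789.2 at -2.19 (SE 0.24), MSTRG.15295.2 at -2.21 (SE 0.36) and MSTRG.351.2 at 1.92 (SE 0.27). Without ADSC-Exos rabbit 1 the count at an unadjusted p under 0.05 was 62, and it was 16 without ADSC-Exos rabbit 3.

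**Figure D3:**
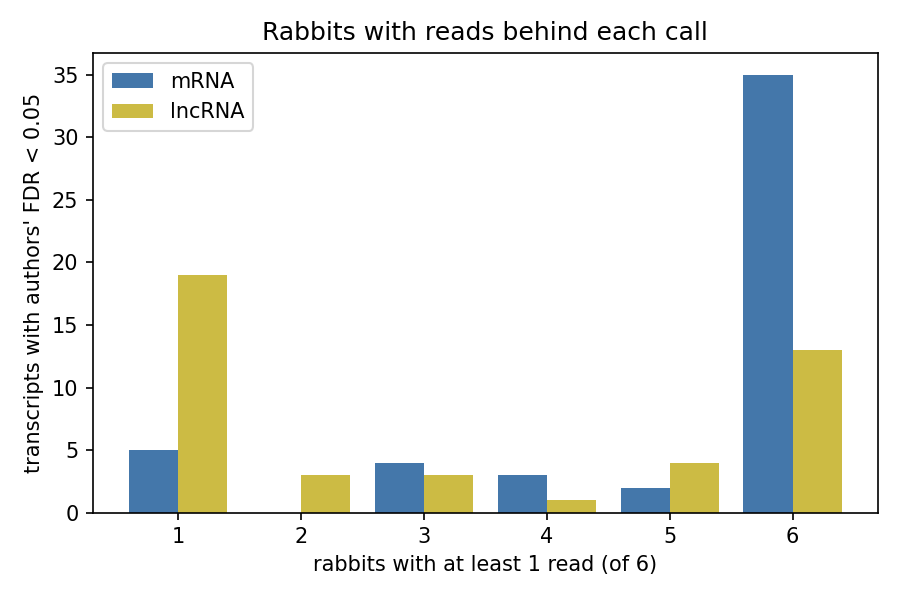
Number of transcripts with an authors' FDR under 0.05 (vertical axis) by the number of the 6 rabbits with at least 1 read (horizontal axis), for mRNAs (blue) and lncRNAs (yellow). Of the mRNA calls 35 had reads in all 6 rabbits, and of the lncRNA calls 13 had reads in all 6 and 19 in 1.

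The third comparison concerned circRNAs, and none was called in the authors' deposited table, where the FDR was 0.82 for all 1694 and the smallest p was 0.080. A circRNA of PPP2R5A, a phosphatase subunit gene, on chromosome 16 from 60682139 to 60687565, had no reads in control rabbits and 3, 5 and 3 reads in ADSC-Exos rabbits. A circRNA of EED, a gene of the Polycomb repressive complex, on chromosome 1 from 130432717 to 130442475, had no reads in ADSC-Exos rabbits. In control rabbits it had 4, 2 and 5 reads. Both are annotated as exonic. Of the listed circRNAs 911 were higher and 783 lower. The arms did not overlap for 12.0%; selection and tied zeros leave no chance value to set beside this share, and the 10% of untied, unselected values does not apply.

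Limma called these 2 circRNAs (adjusted p = 0.045 for each, over the table). The listed circRNAs were selected for their fold change and the number tested is not known, so this adjustment is lenient. Over all circRNAs tested the 2 might not pass. At an unadjusted p under 0.05 there were 283. That count was 516 without ADSC-Exos rabbit 1 and 175 with a pseudocount of 0.01. The median circRNA had 3 reads over all 6 rabbits, and 78.9% had at most 5, so counting error is large beside these differences. The count of calls ran from 0, with a pseudocount of 0.01, to 430, without ADSC-Exos rabbit 1. CircRNAs of PFDN2, ENOSF1, INO80, SASS6, BPTF, ABCA6, CTPS2 and DCAF12 had the next smallest limma p and did not pass.

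The treated rabbits were not alike. Over the 242 mRNAs listed higher, the median log2 distance from the control mean was 0.42 in ADSC-Exos rabbit 1, 2.14 in rabbit 2 and 2.13 in rabbit 3. Rabbit 1 was the lowest of its arm for 83.9% of them, where chance gives 33.3%. Over the 179 mRNAs listed lower, the medians were -1.42, -1.95 and -1.67, and rabbit 1 was the least changed for 41.9%. PDK4, CES4A and TNNT2 each had their lowest treated value in rabbit 1.

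**Figure D4:**
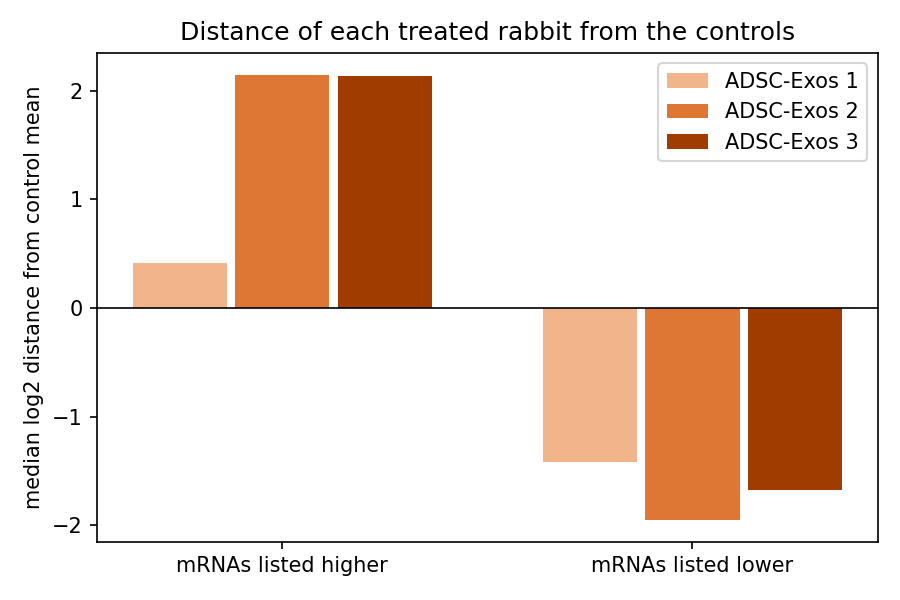
Median log2 distance of each ADSC-Exos rabbit from the control mean (vertical axis) over the 242 mRNAs listed higher and the 179 listed lower. Each bar is 1 rabbit and shows a median over transcripts, with no error bar. Rabbit 1 lies at 0.42 for the higher set, against 2.14 and 2.13 in rabbits 2 and 3.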

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

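Depth limits the circRNAs most, and the tables hold selected features, so these settings test the selection's stability and not that of all transcripts. The filter at 10, the counts at an unadjusted p under each alternative setting, the settings for the authors' calls, and leaving out a rabbit for locus sums and fold bounds were chosen after seeing the data; leaving out each rabbit for the adjusted calls and the unadjusted threshold for mRNAs were planned. Limma's adjusted mRNA calls stayed at 0 under all settings but leaving out 1 rabbit (0 to 2, the 2 without ADSC-Exos rabbit 1) and a threshold of an unadjusted p under 0.05 (193). Adjusted lncRNA calls stayed at 0 but for 0 to 1 without 1 rabbit. CircRNA calls, 2 as reported, were 0 with quantile normalization, a pseudocount of 0.01 or the mRNA table's size factors, 98 with no size factor, 109 with a pseudocount of 0.1, 128 without the trend and robust options, 7 of 19 features with the filter at 10, and 265 to 430 without 1 rabbit. At an unadjusted p under 0.05, mRNAs (193) were 127 with the filter at 10 and 91 to 311 without 1 rabbit: 92 and 116 without control rabbits 2 and 3, 311, 101 and 91 without ADSC-Exos rabbits 1, 2 and 3. LncRNAs (37) were 16 to 62: 21, 22 and 19 without control rabbits 1 to 3, 62, 17 and 16 without ADSC-Exos rabbits 1 to 3. CircRNAs (283) were 175 with a pseudocount of 0.01, 10 with the filter at 10, which leaves fewer features, and 346 to 516 without 1 rabbit, the 516 without ADSC-Exos rabbit 1. The other causes were not tested. The authors' calls with arms that do not overlap were 38 (mRNA) and 18 (lncRNA) with no size factor; leaving out a rabbit can only keep or raise these counts and tests nothing. In the main fits the filter at 1 removes nothing, so no filter tests nothing. In other settings it left fewer circRNAs: 1120 with no size factor, 1013 with the mRNA table's size factors and 1408 to 1485 without 1 rabbit. The circRNA counts of those settings are therefore over fewer features than the 1694 of the main fit. Without 1 rabbit it also removed a few mRNAs and lncRNAs. The replicate number as a block gave 0 mRNA, 0 lncRNA and 0 circRNA calls, and 169, 36 and 211 at an unadjusted p under 0.05; same-numbered rabbits had correlations of deviations between -0.054 and 0.027, so the numbers name rabbits and do not pair them. For the named features no log2 difference changed sign in any setting that gave a value; 1196 comparisons kept their side of the threshold, 49 moved past it and 8 lost it. Of the 79 named mRNAs and lncRNAs, 8 had reads in 1 rabbit, and such a feature has no value without that rabbit. Of the other 71, 23 had a log2 difference that moved by more than 1.5 times without 1 rabbit, 15 without a treated and 8 without a control rabbit. Count tests and their factors were planned for raw counts and were not run on the log2 values, though whole reads could be recovered from these. Set tests were not run, as the features are selected. The TGFB1 difference was not tested, as TGFB1 was not analysed here.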

Other observations

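All the tests in this part were chosen only after the values they rest on had been looked at. The erythroid list was extended, and other genes named, because of their values; 3 further groupings of genes picked in that way were tested once for direction and are left out, since their direction was known when they were made. Of 155 annotation terms with enough listed members, oxidoreductase activity was the most one-sided, with 12 transcripts higher and 0 lower, and it did not pass (Fisher's exact test, two-sided, p = 0.0016; adjusted p = 0.24). Its members included the dual oxidase genes DUOX1 and DUOX2, at differences of 1.17 and 1.59, HSD11B1, which regenerates active glucocorticoid, at 1.10, and the steroid reductase gene SRD5A2 at 1.08. None of these 4 was called in the authors' deposited table (FDR 0.58, 0.14, 0.33 and 0.36), and the arms of DUOX1, DUOX2 and HSD11B1 overlapped. Single rabbits moved them: without ADSC-Exos rabbit 1 DUOX1 was at 2.08, DUOX2 at 2.55 and HSD11B1 at 1.77, without ADSC-Exos rabbit 2 DUOX1 was at 0.53 and DUOX2 at 0.96, and without control rabbit 3 SRD5A2 was at 0.70. AOX1, the aldehyde oxidase, had 11627 and 9189 reads in ADSC-Exos rabbits 2 and 3 and 1353 in rabbit 1, against 2260 to 2493 in the controls. Another of the 12, ABL2, had reads of its listed transcript in ADSC-Exos rabbit 3 alone, so its direction rests on 1 rabbit.

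Of the 6 pairs of a listed lncRNA and a listed mRNA within 3 kb, 5 had the same direction (exact binomial p = 0.22, two-sided); 2 of the pairs share PCTP, so they are not independent. MSTRG.10286.1 differed by 3.22 and its neighbour PCTP, a phosphatidylcholine transfer protein, by 1.27. MSTRG.4811.1 differed by 1.81 and its neighbour CYR61, a matricellular protein, by 1.48. Of these only MSTRG.10286.1 was called in the authors' deposited table (FDR 0.0016); PCTP, MSTRG.4811.1 and CYR61 were not (FDR 0.084, 0.057 and 0.090), and the arms of PCTP and CYR61 overlapped. Without ADSC-Exos rabbit 3 PCTP differed by 0.83. Of 13 circRNAs whose host gene was a listed mRNA, 8 had the direction of the mRNA.

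Of the listed mRNAs and lncRNAs, 52 had at least 100 reads in 1 rabbit and none in another, and 30 of them were among the 92 calls in the authors' deposited table. Only 2, MSTRG.8344.3 and MSTRG.4218.1, had reads in all 3 rabbits of 1 arm and none of the other. That share of 3.85% (exact 95% interval 0.469% to 13.2%) argues against a complete switch in all 3 rabbits of an arm for most of the set. The interval treats the transcripts as independent, though 14 of them share 7 loci. A switch in fewer rabbits fails this count by its rule, as with MSTRG.10286.2 at 0, 24 and 104 reads in ADSC-Exos rabbits alone. Another 23 had reads in 1 rabbit only, 10 of them in a control and 13 in an ADSC-Exos rabbit. The count therefore cannot decide on treatment effects in part of an arm. A candidate explanation is that reads of 1 locus were assigned to different transcript models in different rabbits. In line with it for lncRNAs, 14 of the 35 lncRNAs among them had another listed transcript at their locus against 8 of the other 98 lncRNAs (Fisher's exact test, odds ratio 7.5, p = 5.5e-05), though these 14 come from 7 loci and are not independent. None of the mRNAs among the 52 had one, so the pooled comparison, 14 of 52 against 20 of 502 (odds ratio 8.88), rests on the lncRNAs and mixes 2 tables. At 1 locus MSTRG.8344.4 and MSTRG.8344.6 had reads in control rabbit 2 alone, 3151 and 3349, while MSTRG.8344.3 had them in ADSC-Exos rabbits and MSTRG.8344.5 in all 6; the sum of these 4 listed transcripts differed by -1.13 (SE 0.83) with overlapping arms, and by -0.34 without ADSC-Exos rabbit 1. The explanation is not settled for the 14 either. Summed over listed transcripts, MSTRG.4370, MSTRG.6183 and MSTRG.15037 had at least 134 reads in every rabbit. MSTRG.12994 still had 9969, 1072 and 9360 reads in control and 67, 104 and 4079 in ADSC-Exos rabbits. MSTRG.10435 had 439, 1257 and 1 against 247, 1 and 0, and MSTRG.10286 had 8, 8 and 6 against 10, 209 and 310. Shifts among listed transcripts alone do not account for such sums. For the other 38 transcripts the explanation also stays open.

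The 6 erythroid transcripts had log2 differences from -1.13 to -3.25, and 3 of them, of HBB2, BPGM and ALAS2, were called lower in the authors' deposited table. CA1, HEMGN and the ALAS2 transcript at -3.25 were not called there (FDR 0.19, 0.25 and 0.33), and limma called none. Without control rabbit 3 HEMGN went from -1.21 to -0.77. That rabbit had the highest control value of each of the 6. HBB2 had 31043 reads there, against 10733 and 12815 in control rabbits 1 and 2. The sum of the 2 ALAS2 transcripts went from -1.95 to -1.40 without control rabbit 3. The size of these differences therefore rests in part on 1 rabbit. Less blood in the tissue taken from treated scars may explain the lower values. Within the arms the 6 moved together, with a median pairwise correlation of 0.755, to which their shared rise in control rabbit 3 contributes. That was above 98.35% of 10000 random sets of listed mRNAs. With 1 transcript per gene the correlation was 0.797 and for the 4 of the fixed list 0.777. The random sets were not matched for direction or read depth. They cannot show whether other lower mRNAs with as many reads move together as closely. Correlated transcripts would also follow from a shared erythroid programme, and whether treatment changed vessels or bleeding, or the tissue was taken differently, stays open.

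ADSC-Exos rabbit 1 lay near the controls for the mRNAs listed higher but not for those listed lower (least changed for 83.9% against 41.9%, Fisher's exact test p = 2.7e-19 across transcripts, which are not independent). A wrong size factor for that rabbit, acting alone, would need 1 shift for both sets. The median shift that brings it to the other treated rabbits was 1.63 (95% bootstrap interval 1.41 to 1.76) for the higher set. For the lower set it was -0.36 (-0.57 to -0.13), which argues against a wrong size factor as the sole cause. The intervals resample transcripts, which are not independent, and leave out the spread between rabbits. A wrong size factor combined with another difference is not excluded. The labels give no group within the arm, so no biological explanation was tested, and whether that rabbit responded less or rabbits 2 and 3 share something else stays open.

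Other splits of the 6 rabbits into 3 and 3 are too few, 10 in all, for a share under 0.05. At a limma p under 0.05, 1 of the 10 splits, the real one, gave as many mRNAs (193, highest other 51), as many lncRNAs (37, highest other 12) and as many circRNAs (283, highest other 16). The features were selected on the real split, which favours it by construction.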
